A study of Mus musculus with 4 samples.

How the data were processed

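Hypothalamic gene expression was measured with an Affymetrix whole-transcript array in male CDF1 mice, a BALB/c by DBA/2 cross, 20 days after subcutaneous inoculation of C26 cells. C26 is a mouse colon adenocarcinoma line used as a model of cancer cachexia, the loss of body mass that accompanies some tumours. Per the labels, tumour-bearing mice received 500000, 1000000 or 2000000 cells (0.5M, 1M and 2M) in 0.2 ml of buffered saline and controls received a sham injection of the same volume. RNA was pooled within each group before hybridization, from 4 control animals, 4 animals given 0.5M and 3 animals given 1M. The sample of 2M is recorded as a single animal, although its title calls it pooled. Each group was therefore 1 array, with no replicate. The protocols give 100 ng of RNA per array and an RNA integrity number above 8.

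The deposited table holds log2 expression values, 1 per probe set and array, made by the authors with RMA, per the submitters' processing notes. RMA subtracts background, aligns the intensity distributions of all arrays by quantiles and summarises the probes of each probe set. Quantile alignment removes any change common to all transcripts. The RMA version, its software and the arrays it was run over are not given in the sources used here. The table held 35556 probe sets and 0 missing values. The annotation table of the platform listed 23410 of them, 21789 with 1 gene symbol and 1621 with several. The other 12146 were unnamed here and were used only for a count. Of the probe sets with 1 symbol, 21698 matched the mouse reference table of assembly GRCm38.p6 by Entrez number, 91 did not, and 0 symbols changed. No genome build was named for the values, so no coordinates are printed.

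Probe sets with exactly 1 symbol gave 19938 genes. For the 999 genes with several probe sets, the one with the highest mean over the 4 arrays stood for the gene. Counts and tests used the 11963 genes whose mean reached the 40th percentile, 6.59 log2. Array medians were 6.75 log2 in the control and 6.72, 6.77 and 6.75 at 0.5M, 1M and 2M, and the number of arrays limits the precision. Each tumour-bearing array was compared with the control by the difference of log2 values. Genes at least 0.5 log2 away, a 1.41-fold difference, were counted with no p-value, since 1 array stood against 1. Two-sided tests with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05) were made for the 3 tumour-bearing arrays against the control array and for a linear trend with the number of injected cells. Each had 2 residual degrees of freedom. The spread in the first was that between cell numbers and pool sizes, and the lone control array was assumed to vary like the others. In the trend, the single animal of 2M carried most of the weight. The control entered it as 0 cells, so a step between control and tumour-bearing arrays can also give a slope. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining values and plots.

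Before the data were examined, 32 gene lists were fixed for appetite, neuroendocrine, inflammatory, metabolic and cell type markers, including neighbouring tissues that a dissection could hold. The number of table columns with no sample was 0. Of their 540 genes, 494 were analysed. A list's shift was the median difference of its measured members from control, and its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. Percentiles below 2.5 or above 97.5 were called shifted, as a description of these arrays. Among 32 lists of randomly drawn genes, 1.6 would lie outside by chance. The median of a list whose genes vary together can vary more, so chance can place more of these lists outside. Only members past the filter were tested by limma, for example 2 of 11 in the blood list and 5 of 11 in the pituitary list. Members that passed were also counted with the p-values adjusted over the tested members of the list, called the list alone below. This was not corrected for the 32 lists or the 2 tests, so it is weaker than a pass over all genes. Counts at an unadjusted p under 0.05 are to be read beside the count over all genes given in the results. A further 4 lists were added after the data were seen. Because all 3 differences share the control array, agreement between them was set beside 100 simulations of unchanged arrays with a shared control. Their noise came from the spread of the 3 tumour-bearing arrays in the limma fit, so they hold no extra deviation of the single control pool.

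The fixed rule for named genes took 8 appetite peptides in any case and every appetite peptide at least 0.5 log2 from control in any array. It also took the 10 genes highest and the 10 lowest by the smallest of the 3 differences, the 5 highest and 5 lowest per cell number, up to 4 members per list with the largest mean difference and the 10 genes with the smallest p in each limma test. The rule took 162 genes, and which of them the text names was decided after their values were seen. Agrp was among the 8 peptides but was unnamed by the annotation and is not analysed here. List members named outside this rule, namely Fkbp5, Sgk1, Hif3a, Zbtb16, Mbp, Crym and Cga, and all members named from the 4 added lists, were chosen after their values were seen. The fits were tested on simulated data. For 11963 genes, with 200 changed, limma recovered 66% of genes changed by 0.5 log2 and 100% of those changed by 1 log2 in the tumour comparison, where 9 of 141 and 21 of 221 calls were unchanged genes. In the trend it recovered 15.5% and 99.5% of genes changed by 0.5 and 1 log2 at the highest cell number. Of the trend calls, 5 of 36 and 12 of 211 were unchanged genes. The simulated arrays had normal noise with the SD of each gene in the limma fits, so these recoveries need not hold in the data. Plin4, at 1.42 log2 in the data, did not pass the tumour comparison. Of 100 unshifted random lists, 6 fell outside the central 95%, against 100 of 100 lists shifted by 0.3 log2. Such random draws do not cover lists whose members vary together. Alternatives covered the filter (none or the 60th percentile), cyclic loess, median centring, the mean of a gene's probe sets, thresholds of 0.3 and 1 log2, a robust prior with an intensity trend in eBayes, ranked cell number, other list summaries, and leaving out each array. Alternatives that left out the 0.5M or 1M arrays from the list shifts and the counts over all 3 arrays, or left out small RNA genes, were chosen after seeing the data.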

Results

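The pilot part of the study asked how hypothalamic transcripts, those of appetite regulators among them, differ in mice bearing increasing loads of C26 colon adenocarcinoma cells. Total RNA of the hypothalamus was profiled on 4 arrays. The control array held pooled RNA of 4 sham-injected mice, and the others held RNA of 4 mice given 500000 cells (0.5M), 3 mice given 1000000 cells (1M) and 1 mouse given 2000000 cells (2M). Mice were killed on day 20, at 10 to 11 weeks of age. Across probe sets, the arrays correlated with each other at 0.984 to 0.994. No group had a replicate array, so every difference given for 1 cell number is a difference between 2 arrays without a replicate check.

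In the comparison of tumour-bearing with control hypothalamus, 6 genes rose and 0 fell by limma. Lcn2, which encodes the secreted siderophore-binding protein lipocalin-2, was 2.51 ± 0.29 log2 above control (SD over the 3 tumour-bearing arrays), a 5.69-fold difference, with an adjusted p of 0.0327 in limma. Lrg1, a secreted acute-phase glycoprotein, was 2.00 ± 0.16 log2 higher (limma adjusted p = 0.0198), and Scgb3a1, a secretoglobin, 2.17 ± 0.13 log2 higher (limma adjusted p = 0.011). Osmr, the receptor subunit for oncostatin M, was 1.06 ± 0.04 log2 higher (limma adjusted p = 0.0327). Its standard error by limma was 0.09. The SDs over tumour-bearing arrays, here and below, hold no uncertainty of the control array. The other 2 genes were the long non-coding RNA genes Gm10644, at 1.21 ± 0.06 log2, and Gm10874, at 1.06 ± 0.05 log2. All 6 were higher than control in 3 of 3 tumour-bearing arrays. In the control array Lcn2, Lrg1 and Scgb3a1 stood at 6.02, 5.99 and 5.94 log2, below the filter value of 6.59. These genes passed the filter only through the tumour-bearing arrays. Among the genes that did not pass, the small RNA gene Snora44 was 0.86 log2 higher and Plin4, a lipid droplet protein gene, 1.42. The platelet chemokine gene Ppbp was 1.25 log2 higher, the endothelial gene Vwf 0.75 and the erythroid haem synthesis gene Alas2 0.85, and they did not pass either. At an unadjusted p under 0.05, limma gave 1292 genes, and 1263 with the 1M array set against the other arrays in place of the control. Without the filter 1 gene was called and with the 60th percentile filter 2, and without the 1M array 3 were called, since Osmr, Gm10644 and Gm10874 no longer passed. Without the 0.5M array, and likewise without the 2M array, 6 were called, with Osmr and Gm10874 lost and 2 others gained.

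A count by size over the 3 arrays gave 36 genes at least 0.5 log2 above control in all of them and 14 at least 0.5 log2 below. Beside the called genes, the higher set held Plin4, Ppbp, Oxt, Htr6, Vwf and Alas2, and 11 of the 36 were small RNA genes, among them Snord49b at 1.24 ± 0.19 log2 and Snora44 at 0.86 ± 0.04. The lower set was led by Gm8624, a pseudogene, at -0.94 ± 0.22 log2, Fabp7, a fatty acid-binding protein of astrocytes and radial glia, at -1.07 ± 0.62, and Slc7a11, the cystine-glutamate exchanger, at -0.84 ± 0.21. Car4, a carbonic anhydrase (-0.55 ± 0.03), Uqcrb, a subunit of respiratory complex III (-0.66 ± 0.16), Homer2, a postsynaptic scaffold gene (-0.79 ± 0.23), Rrs1 (-0.80 ± 0.16), Mzt1 (-0.82 ± 0.19), Ncbp2 (-0.60 ± 0.07) and BC065397 (-0.56 ± 0.05) followed. With probe sets averaged, Mzt1, Homer2 and BC065397 stood at -0.55, -0.32 and -0.29 log2. None of these lower genes passed limma. Simulated unchanged arrays sharing a control gave 1.75 higher and 1.42 lower genes on average, with maxima of 5 and 4. These simulations hold no extra deviation of the control pool, so they set no upper bound for chance. With the 0.5M, 1M or 2M array taken as the lone one, 3, 23 and 19 genes set it apart from the other arrays, against 50 for the control. Without the 0.5M array the counts were 81 higher and 56 lower, and without the 2M array the lower count was 24.

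**Figure D1:**
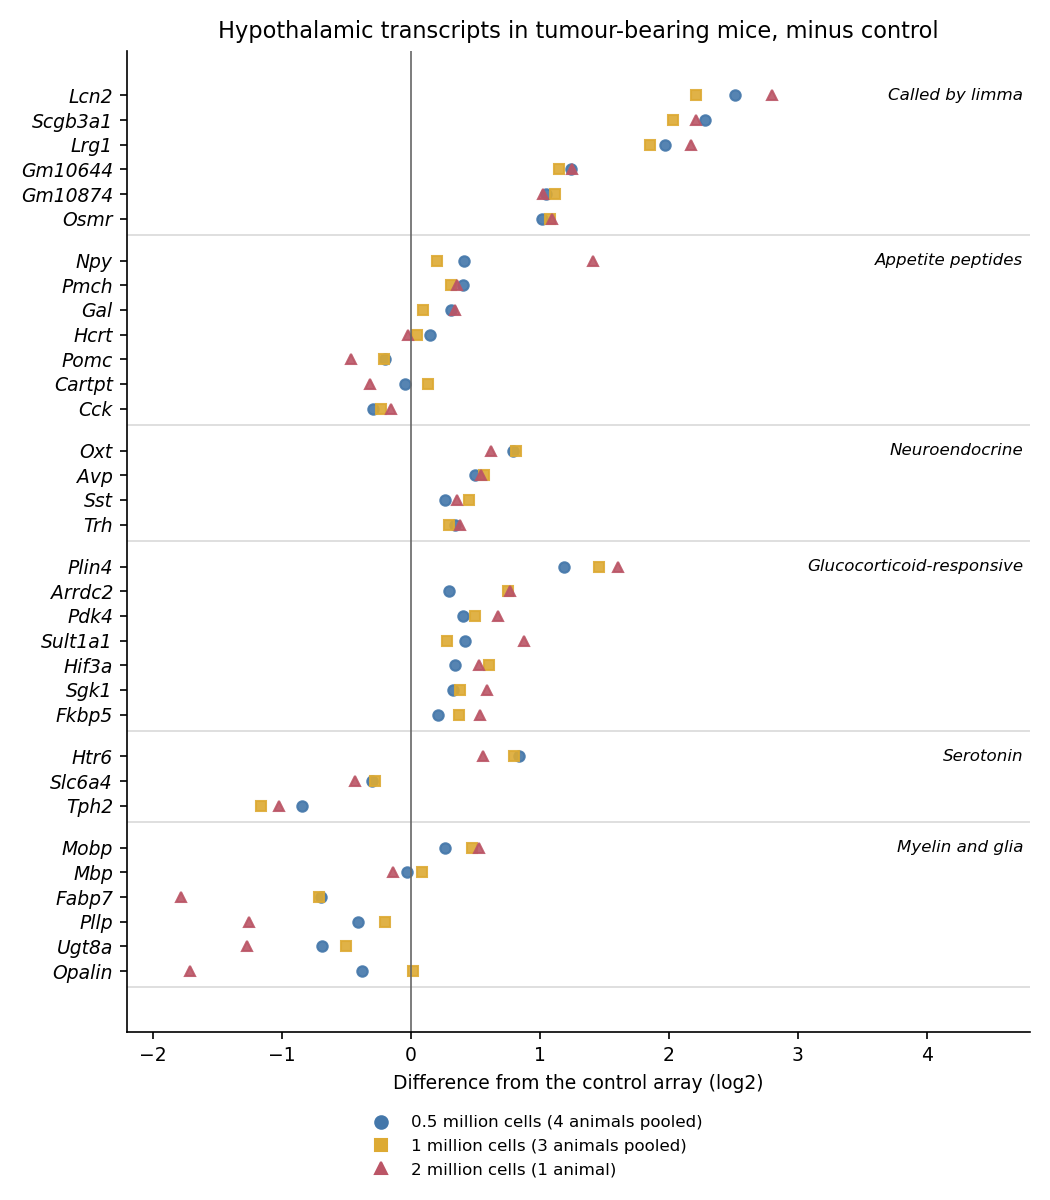
Difference of each tumour-bearing array from the control array, in log2, for the 6 genes called by limma and for members of 5 gene groups. Each point is 1 array without a replicate, circles for 0.5M, squares for 1M and triangles for 2M; Lcn2 lies between 2.21 and 2.80, and Npy reaches 1.41 at 2M.

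Orexigenic neuropeptides, which stimulate feeding, had medians above control in the 3 tumour-bearing arrays. Npy, the feeding peptide of arcuate neurons, was 0.41, 0.20 and 1.41 log2 above control at 0.5M, 1M and 2M, the last a 2.67-fold difference in a single animal. Pmch, the precursor of melanin-concentrating hormone, was 0.40, 0.31 and 0.36 log2 higher, and Gal, the galanin gene, 0.31, 0.10 and 0.34. Hcrt, the orexin precursor, differed by 0.15, 0.05 and -0.03, and Qrfp by -0.16, 0.26 and 0.32. Of the 8 measured members, 3 were higher and 1 was lower in all 3 arrays, where chance gives 25% in each direction because the control is shared. The list median of 0.15, 0.22 and 0.24 log2 lay at percentiles 99.56, 98.25 and 99.83 of random lists for the 3 cell numbers, and that of the mean over arrays, 0.13, at 96.3. The latter was 0.07 (percentile 85.6) without the 1M array, and past the random range at 0.22 (percentile 99.4) without the 0.5M array and 0.15 (percentile 98.2) without the 2M array. In limma, 0 members passed in the tumour comparison, whether adjusted over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. In the trend, Npy passed adjusted over the list alone only (0.67 ± 0.13 log2 per 1000000 cells, SE, limma adjusted p over all genes 0.38). For the lists that follow, counts by limma are those of the tumour comparison unless the trend is named.

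Anorexigenic neuropeptides, which restrain feeding, were shifted in no common direction. Pomc, the precursor of alpha-MSH, was -0.20, -0.21 and -0.46 log2 from control at 0.5M, 1M and 2M. Cartpt differed by -0.05, 0.13 and -0.32 and Cck by -0.30, -0.23 and -0.15. Crh, the corticotropin-releasing hormone gene, differed by -0.21, -0.20 and 0.67, and Gcg, the proglucagon gene, by 0.19, 0.52 and 0.39, both below the filter value. Trh was 0.34, 0.29 and 0.38 log2 higher, and Ucn3, below the filter value, 0.20, 0.46 and 0.33. Among 19 measured members, 5 were higher and 4 lower in all 3 arrays, and 0 passed limma, adjusted over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05. The median of the mean differences was 0.07 log2 (percentile 77.1), and that of the 11 members past the filter was -0.08 (percentile 4.20). Receptors for appetite and metabolic hormones lay close to control, with a median of 0.06 log2 over 25 members (percentile 76.7), 10 higher and 5 lower in all 3 arrays, and 0 passing limma by either adjustment, and with 0 at an unadjusted p under 0.05. Npy4r, below the filter value, was 0.54 ± 0.04 log2 higher, Brs3, also below it, 0.26 ± 0.26 and Ghsr, the ghrelin receptor gene, 0.21 ± 0.14, while Glp1r was -0.20 ± 0.20 from control.

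Among neuroendocrine peptide genes, 8 of 14 were higher than control in all 3 tumour-bearing arrays and 0 were lower. Oxt, the oxytocin gene, was 0.79, 0.81 and 0.62 log2 above control and Avp, the vasopressin gene, 0.50, 0.56 and 0.55. Sst, the somatostatin gene, was 0.36 ± 0.09 log2 higher on average and Vip, below the filter value, 0.43 ± 0.10. In limma 0 passed over all genes, with 4 at an unadjusted p under 0.05, and Oxt, Avp, Sst and Trh passed adjusted over the list alone. The list median of 0.17, 0.20 and 0.22 log2 lay at percentiles 100, 98.3 and 100 for the 3 cell numbers, and that of the mean over arrays, 0.10, at 94.2. The latter passed the random range without the 1M array (0.15, percentile 99.6) and with members past the filter only (0.16, percentile 99.4). Pituitary markers, described further on, were also higher, at a median of 0.22 log2 (percentile 99.5). Markers of hypothalamic neuron regions stood at a median of 0.09 log2 (percentile 94.7, 18 members, 7 higher and 1 lower in all 3 arrays, 0 passing limma by either adjustment, 3 at an unadjusted p under 0.05), with Hmx3 at 0.40 ± 0.28, Otp at 0.37 ± 0.09, Lhx6 at 0.36 ± 0.07 and Barhl1 at -0.31 ± 0.19. Without the 2M array the median was 0.12, past the random range (percentile 97.9). In the thyroid hormone list, Hr was 0.49 ± 0.16 log2 higher, Klf9 0.42 ± 0.12 and Dio2, the deiodinase that activates thyroxine, 0.36 ± 0.10. These 3 genes and Trh passed limma adjusted over the list alone and 0 passed over all genes, with 4 at an unadjusted p under 0.05. The list median was 0.12 log2 (11 members, percentile 96.2), with 5 higher and 2 lower in all 3 arrays. It was 0.04, 0.08 and 0.24 log2 at 0.5M, 1M and 2M, and without the 2M array it turned to -0.02 (percentile 19.3). It passed the random range without the 0.5M array (0.17, percentile 98.2), without the 1M array (0.11, percentile 97.6) and with cyclic loess (0.13, percentile 98.4).

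Serotonin genes went both ways. Htr6, a serotonin receptor gene, was 0.84, 0.80 and 0.56 log2 higher and was the 1 member that passed limma adjusted over the list alone (adjusted p over all genes 0.34). Tph2, the rate-limiting enzyme of neuronal serotonin synthesis, was -0.85, -1.16 and -1.03 log2 from control and Slc6a4, the serotonin transporter, -0.30, -0.28 and -0.43, both below the filter value and outside the test. Maob was -0.40 ± 0.19 log2 from control. The fixed lists held none for midbrain or hindbrain markers. The share of such tissue in each dissection was therefore not checked for the serotonin and dopamine genes. Of the 21 members 6 were higher and 7 lower in all 3 arrays, with a median of 0.03 log2 (percentile 49.4), a mean of -0.03, and a median of -0.02 with cyclic loess. In the dopamine list Th, tyrosine hydroxylase, was -0.21, -0.71 and -0.45 log2 from control and the transporter gene Slc6a3 -0.20, -0.71 and -0.21, while Drd1 was 0.43, 0.05 and 0.07 log2 higher. The 9 members had a median of 0.06 log2 (percentile 67.7) and a mean of -0.04, and medians of 0.05, 0.05 and -0.13 at 0.5M, 1M and 2M (percentile 1.68 at 2M). Without the 0.5M array the median was -0.01. In all 3 arrays 2 members were higher and 3 lower, and 0 passed limma by either adjustment, with 1 at an unadjusted p under 0.05. Among transmitter genes, the vesicular glutamate transporter genes Slc17a7 and Slc17a6 were -0.50 ± 0.13 and -0.30 ± 0.07 log2 from control, and the GABA and glutamate list had a median of -0.06 (15 members, percentile 8.15, 2 higher and 5 lower in all 3 arrays, 0 passing limma by either adjustment, 2 at an unadjusted p under 0.05), and of -0.14 at 1M (percentile 1.35).

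Genes of the interleukin-6 and acute-phase response were higher as a group. Lcn2, Lrg1 and Osmr rose, as given above. Hamp, the hepcidin gene, below the filter value, was 0.28, 0.74 and 0.98 log2 above control, from a low control value of 3.30. Of the 26 measured members 14 were higher and 0 lower in all 3 arrays, and 3 passed limma over all genes and 3 adjusted over the list alone. The median of 0.15 log2 lay at percentile 99.7. Only 9 of the 26 members lay past the filter, with a median of 0.17 log2 (percentile 99.1). The cytokine and NF-kB list stayed near control (median 0.03 log2, 24 members, percentile 33.4), with Nfkbia at 0.48 ± 0.15, Il6ra at 0.31 ± 0.12, and Il1rn at -0.31 ± 0.09 and Il1a at -0.29 ± 0.44, both below the filter value. In all 3 arrays 7 members were higher and 4 lower, and 0 passed limma by either adjustment, with 2 at an unadjusted p under 0.05. Interferon response genes had a median of -0.12 log2 (21 members, percentile 0.01), and of -0.15, 0.03 and -0.16 at 0.5M, 1M and 2M, with 7 lower and 2 higher in all 3 arrays. B2m, the light chain of MHC class I, was -0.51 ± 0.21 log2 from control, and the interferon-induced GTPase genes Gbp4 and Iigp1, below the filter value, -0.40 ± 0.18 and -0.26 ± 0.21. Of this list 0 passed limma by either adjustment and 1 had an unadjusted p under 0.05, and the median lay inside the random range without the 2M array (-0.03, percentile 4.04) and with members past the filter only (-0.07, percentile 4.45).

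Glucocorticoid-responsive genes were the list with the highest shift for the mean over arrays, at a median of 0.42 log2. At 0.5M the pituitary list stood slightly higher, at 0.28 log2. Plin4 was 1.19, 1.46 and 1.61 log2 above control, Arrdc2 0.29, 0.75 and 0.77, and Sult1a1 0.42, 0.28 and 0.88. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, was 0.21, 0.37 and 0.53 log2 higher and Sgk1, a serum- and glucocorticoid-induced kinase gene, 0.33, 0.38 and 0.59. Of 21 measured members, 17 were higher and 0 lower in all 3 arrays. The median was 0.27, 0.38 and 0.49 log2 at 0.5M, 1M and 2M, each at percentile 100. Lcn2 alone passed limma over all genes, and 9 members passed adjusted over the list alone, namely Sgk1, Zbtb16, Plin4, Pdk4, Klf9, Arrdc2, Lcn2, Hif3a and Nfkbia. In the trend, 0 passed over all genes and 11 adjusted over the list alone. Among the 11, Fkbp5, Sgk1, Plin4 and Arrdc2 rose in the order of cell number. Lcn2, at 2.51, 2.21 and 2.80 log2, and Sult1a1 did not, since a step from control alone can also give a slope. The single animal of 2M carries most of the weight in this trend too. Clock genes stood at a median of 0.05 log2 (17 members, percentile 82, 7 higher and 4 lower in all 3 arrays, 0 passing limma by either adjustment, 1 at an unadjusted p under 0.05), with Cry2, Tef, Dbp and Per2 at 0.25 ± 0.12, 0.24 ± 0.02, 0.22 ± 0.20 and 0.22 ± 0.05. Immediate early genes had a median of -0.06 (16 members, percentile 2.55), and of -0.10, -0.01 and -0.10 at 0.5M, 1M and 2M (percentiles 1.79, 8.81 and 1.05), with 0 higher and 5 lower in all 3 arrays, Egr1 at -0.36 ± 0.17 and Fos, below the filter value, at -0.27 ± 0.14. Of them 0 passed limma by either adjustment in the tumour comparison and 1 had an unadjusted p under 0.05. The median of the mean passed the random range with cyclic loess (-0.09, percentile 1.72), without the 0.5M array (-0.06, percentile 2.43) and without the 1M array (-0.11, percentile 0.67), as did the mean of members (-0.07, percentile 1.31). In the trend, Egr1, downward, and Dusp1, upward, passed adjusted over the list alone.

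In the fatty acid and ketone list, Fabp7 was -0.70, -0.72 and -1.78 log2 from control and the desaturase gene Scd1 -0.34 ± 0.12, whereas Pdk4, a kinase that blocks pyruvate oxidation, was 0.52 ± 0.14 higher and Angptl4, a lipoprotein lipase inhibitor gene, 0.44 ± 0.19. The list median was -0.06 log2 (17 members, percentile 5.02, 4 higher and 8 lower in all 3 arrays, 0 passing limma by either adjustment in the tumour comparison, 5 at an unadjusted p under 0.05), and -0.10 at 2M (percentile 1.76). Without the 1M array it was -0.09, past the random range (percentile 1.41). In the trend, Pdk4 (0.30 log2 per 1000000 cells) and Fabp7 (-0.84) passed adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.08 log2 (percentile 1.97), with 13 of 20 lower and 2 higher in all 3 arrays. Cycs, cytochrome c, was -0.40 ± 0.11 log2 from control, or -0.13 when its probe sets were averaged, Atp5b -0.26 ± 0.06, Sdha -0.26 ± 0.04 and Ndufa1 -0.25 ± 0.10. The endoplasmic reticulum stress list also had a median of -0.08 (19 members, percentile 1.70), with 5 higher and 8 lower in all 3 arrays, Hsp90b1 at -0.38 ± 0.21 and Xbp1 at 0.29 ± 0.10. In these 2 lists 0 members passed limma by either adjustment, with 3 and 1 at an unadjusted p under 0.05, and with cyclic loess scaling the medians lay inside the random range, at percentiles 2.60 and 3.88. Without the 2M array the oxidative phosphorylation list was at percentile 3.01, and the stress list was at 4.93 without the 0.5M array and 17 without the 1M array.

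Myelin genes were lower in the 2M array. Opalin was -1.72 log2 from control there, Ugt8a, the enzyme of galactocerebroside synthesis, -1.27 and Pllp -1.26, while Mobp, myelin-associated basic protein, was 0.53 higher and Mbp -0.14. The median of the 15 myelin and oligodendrocyte markers was -0.18, 0.02 and -0.43 log2 at 0.5M, 1M and 2M, at percentiles 0, 61.2 and 0, with 7 lower and 1 higher in all 3 arrays. Of them 0 passed limma by either adjustment in the tumour comparison, with 2 at an unadjusted p under 0.05, and 7 passed the trend adjusted over the list alone, Mobp upward and the other 6 downward. The single animal of 2M carries most of the weight in that trend, and the list medians did not fall in the order of cell number. Oligodendrocyte precursor markers had a median of 0.01 log2 (9 members, percentile 50.4) and a mean of -0.03. Of these, 2 were higher and 1 lower in all 3 arrays, with Enpp6 at -0.38, 0.05 and -0.76. The microglial genes Cx3cr1 and Itgam were -0.64 and -0.65 log2 from control at 2M, Itgam being below the filter value, while the complement gene C1qc was 0.41 higher. The 19 microglia and macrophage markers had a median of -0.02 log2 over the arrays (percentile 8.82), 0.06 for those past the filter and -0.12 at 2M (percentile 0.16), with 5 higher and 8 lower in all 3 arrays. It passed the random range without the 0.5M array (-0.09, percentile 0.26) and with cyclic loess (-0.08, percentile 2.03). Astrocyte markers had a median of -0.02 (15 members, percentile 34.8), 3 being higher and 6 lower in all 3 arrays, with the water channel gene Aqp4 at -0.49 ± 0.16 and Agt, angiotensinogen, at 0.37 ± 0.17. Endothelial and pericyte markers had a median of 0.03 (17 members, percentile 63.9), 8 being higher and 6 lower in all 3 arrays, and Vwf in the tumour comparison and Itm2a in the trend, downward, passed limma adjusted over the list alone. Tanycyte and ependymal markers had a median of 0.05 (13 members, percentile 57.1), 3 being higher and 3 lower in all 3 arrays, with Gpr50 at -0.57 ± 0.17 and Ccdc153 at 0.35 ± 0.06 passing adjusted over the list alone in the tumour comparison, and Gpr50, downward, and Crym, upward, in the trend. The median was 0.00 for pan-neuronal markers (14 members, percentile 51.5), 3 being higher and 5 lower. In the tumour comparison by limma, 0 members of the oligodendrocyte precursor, microglia, astrocyte and pan-neuronal lists passed by either adjustment, with 0, 1, 3 and 2 at an unadjusted p under 0.05. In the trend, the astrocyte genes Agt, upward, and Slc7a10, downward, passed adjusted over the list alone.

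Markers of neighbouring tissue differed between arrays. Gh and Prl, the growth hormone and prolactin genes of the anterior pituitary, were 4.68 and 3.85 log2 above control at 0.5M, from low control values of 6.13 and 3.95 log2, and 0.72 to 0.78 and 0.55 to 0.56 log2 above it in the other tumour-bearing arrays. Prl lay below the filter value. Pituitary markers as a list had a median of 0.22 log2 (11 members, percentile 99.5), and of 0.28, 0.31 and 0.08 at 0.5M, 1M and 2M, the last inside the random range (percentile 63.6). In all 3 arrays 8 were higher and 2 lower, and Lhb (0.35 ± 0.03) and Ghrhr (0.36 ± 0.06) passed limma adjusted over the list alone. Striatal and basal forebrain markers were at 0.22 log2 in the 0.5M array (13 members, percentile 100), with Ppp1r1b at 0.87 and Pde10a at 0.84, and at 0.05 and 0.07 in the others, with 6 higher and 0 lower in all 3 arrays. The median of the mean was 0.08 (percentile 91.6), and 0.15 (percentile 99.8) without the 1M array. Meningeal and fibroblast markers were lower, with a median of -0.20 log2 (15 members, percentile 0.01) and 10 lower against 1 higher in all 3 arrays. Aldh1a2 (-0.56 ± 0.11) passed limma adjusted over the list alone, and Slc13a4 (-0.45 ± 0.15) and Slc6a13 (-0.43 ± 0.15) did not. Lists for choroid plexus (median 0.06 log2, 14 members, percentile 56), thalamus (0.02, 12 members, percentile 47), cortex and hippocampus (0.07, 14 members, percentile 78.9) and blood cells (0.11, 11 members, percentile 78) lay within the random range for the mean over arrays, the cortical list being at 0.20 (percentile 99.7) at 2M, with 3, 4, 5 and 5 members higher and 3, 4, 3 and 2 lower in all 3 arrays. By limma 0 members of the striatal, choroid plexus and thalamus lists passed by either adjustment, with 0 at an unadjusted p under 0.05 in each. In the cortical list Wfs1 (0.52 ± 0.18), Tbr1 (0.41 ± 0.10) and Nrn1 (-0.37 ± 0.10) passed limma adjusted over the list alone, as did Alas2 in the blood list. Over all 32 lists, 3 were shifted higher than random lists, namely the glucocorticoid, acute-phase and pituitary lists. Another 5 were shifted lower, namely the myelin, meningeal, interferon, oxidative phosphorylation and endoplasmic reticulum stress lists. The lists are not independent, since some genes are in several. Lcn2 is in the glucocorticoid and acute-phase lists, and Trh in the anorexigenic, neuroendocrine and thyroid lists.

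**Figure D2:**
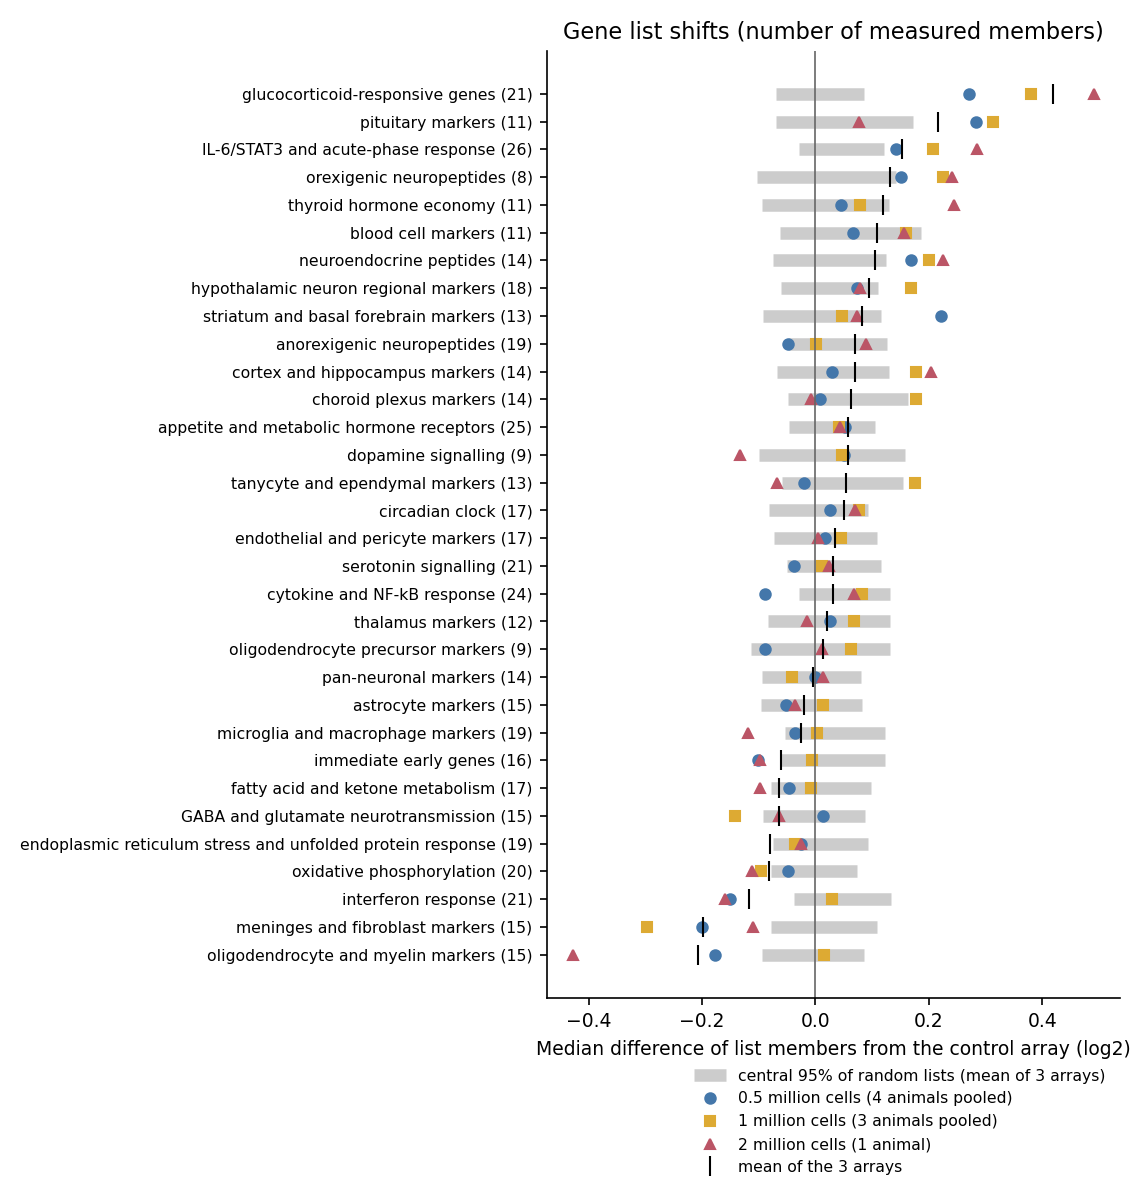
Median difference of the measured members of each of the 32 fixed gene lists from the control array, in log2, per tumour-bearing array (points) and for the mean of the 3 arrays (vertical tick), with the central 95% of medians of matched random lists for that mean (grey bars). Glucocorticoid-responsive genes stand at 0.27 to 0.49 log2, and myelin markers range from 0.02 at 1M to -0.43 at 2M.

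Each cell number was also set against the control alone. At 0.5M 67 genes were at least 0.5 log2 higher and 35 lower, led upward by Gh, Lcn2, Scgb3a1, Lrg1 and Snord49b and downward by Klk6 (-0.76), Rln3 (-0.75), Phgdh (-0.73), Gm8624 (-0.72) and Fabp7 (-0.70). At 1M 195 were higher and 256 lower, a balance that turned to 640 and 318 without the filter and to 1233 and 935 at a threshold of 0.3 log2. The lowest there were Gm10785 (-1.32), Zfp971 (-1.31), Nudt11 (-1.31), Rbm7 (-1.25) and Slc10a4 (-1.21). At 2M 148 were higher and 149 lower. Npy was among the 5 highest genes there, and Fabp7 (-1.78), Opalin (-1.72), Scarna13 (-1.36), Snora16a (-1.30) and Ugt8a (-1.27) were lowest. The SD of the differences over genes was 0.17, 0.24 and 0.21 log2. Between 0.5M and 1M 38 of the higher genes were shared and 24 of the lower, against 1.09 and 0.749 for independent lists and 3.72 and 3.29 in simulations with a shared control. Between 0.5M and 2M 44 and 21 were shared, against 0.829 and 0.436 for independent lists and 3.95 and 3.62 in simulations. Between 1M and 2M 81 and 56 were shared, against 2.41 and 3.19 for independent lists and 4.07 and 3.48 in simulations, and part of the excess may come from the shared control array. Across genes, which are not independent replicates, the differences correlated at 0.60 (0.5M with 1M), 0.73 (0.5M with 2M) and 0.72 (1M with 2M). The simulated mean was 0.50 for each pair, the value that equal noise in all arrays and a shared control give by construction. The covariance of the differences exceeded the simulated one by 0.0141, 0.016 and 0.0254.

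No gene passed limma in the trend with the number of injected cells, with 780 genes at an unadjusted p under 0.05. The 3 smallest adjusted p-values, each 0.108 in limma, belonged to the guide RNA gene Scarna13, at -0.70 ± 0.08 log2 per 1000000 cells (SE), the MHC class II locus H2-Ea at -0.55 ± 0.06 and Fabp7 at -0.84 ± 0.09. Hmcn1 (-0.49 ± 0.06), Snora73b (-0.47 ± 0.06) and Car2 (-0.41 ± 0.06) followed downward, and Phyhd1 (0.63 ± 0.09), Hspb1, a small heat shock protein gene (0.49 ± 0.07), and Stab2 (0.48 ± 0.06) upward. In the plain order of cell number 66 genes stood in strictly rising and 45 in strictly falling order over a range of at least 0.5 log2. The 24 possible orders of the arrays gave 30.75 on average and 1 to 169, with 3 orders reaching 66 and 6 reaching 45. The trend count rested on single arrays. Limma called 24 genes higher and 14 lower without the 0.5M array, 28 and 30 without the 1M array, 0 and 3 without the control and 0 and 0 without the single animal of 2M, and with a robust prior it called 0 and 2, Fabp7 and Scarna13.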

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

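All tests in this part were chosen after the results were seen. Among probe sets that the annotation leaves unnamed, which the gene comparisons do not use, 71 of the 4618 past the filter value were at least 0.5 log2 above the control in all 3 tumour-bearing arrays and 128 at least that far below. What these probe sets measure, and whether control probes are among them, was not established here. Taking another array as the lone one, the others were all higher for 17 probe sets at 0.5M, 282 at 1M and 20 at 2M, so the control is not the array that most stands apart by this count.

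Lcn2, Lrg1, Osmr and Scgb3a1 were higher in all 3 tumour-bearing arrays, by 1.06 to 2.51 log2 in the mean over the arrays. The median difference of 5 neutrophil granule and calprotectin genes, a list written for this test whose members are all in the blood cell list too, was 0.139 log2, and S100a8 and S100a9, abundant transcripts of these cells, stood at 4.19 and 5.80 log2 in tumour-bearing arrays against 3.97 and 5.55 in the control. Since 0 of the 5 passed the filter, a contribution of neutrophils, which carry Lcn2, is not excluded. As to an unusual control array, limma called 6 genes with the control as the lone array, and 1 of the 4 choices of a lone array gave as many, the highest other count being 0, although 1263 genes had an unadjusted p under 0.05 with the 1M array as the lone one against 1292 with the control. With 4 choices no share under 0.05 can arise, so a low reading of these genes in the single control pool cannot be told apart from an effect of the tumour, which stays open and untested.

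Myelin and oligodendrocyte genes were lower in the 2M array, at a median of -0.43 log2. Less myelinated tissue in that dissection stays open as a cause, whole or in part. The SD of the differences, 0.55 log2, was 2.504 times the 0.22 log2 of a single difference between 2 arrays in the limma fit, but 1.72 times without Opalin (-1.72 log2) and Mobp (0.53), the members farthest from the median. Within 2 such SDs of the median lay 11 of the 15. Variation between animals and the tumour load cannot be told apart, because the highest cell number is a single animal; in the pool of 3 animals given 1M the median was 0.015 log2, and in the pool of 4 given 0.5M it was -0.18 (percentile 0).

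Gh was 4.68 log2 above control in the pool of 0.5M, against 0.78 and 0.72 in the other tumour-bearing arrays. Anterior pituitary tissue in this pool is a candidate explanation, and Prl, the other abundant hormone transcript of that gland, was 3.847 log2 higher in the same array, from a low control value of 3.95, against at most 0.56 in the others. The remaining 9 pituitary markers did not follow, with medians of 0.18, 0.23 and 0.03 log2 at 0.5M, 1M and 2M, and Pomc and Cga differed by -0.20 and -0.05 at 0.5M, from control levels of 7.19 and 8.60 log2 that would hide a small share. An effect of the tumour on these hormone genes was not tested.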

How the results depend on the processing

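Over counts and correlations, 89 alternative values stayed within 1.5 times the count, or within the spread of the 3 correlations, and 58 did not. No correlation changed sign, but the balance of higher and lower genes turned at 1M without the filter and at 0.3 log2, and at 0.5M without the filter. At 2M, with 148 higher and 149 lower, it turned without the filter, with median centring (148 and 147) and at both other thresholds. All 17 values each under median centring and under the mean of a gene's probe sets, and all 19 under cyclic loess, were among the 89. For list shifts, 167 kept their direction and their side of the random range, 20 passed it newly and 10 no longer did. Another 16, of 10 lists, changed sign inside that range, those of the anorexigenic, serotonin, dopamine, thyroid, microglia, oligodendrocyte precursor, endothelial, pan-neuronal, choroid plexus and thalamus lists. Of 486 values of single named genes, 482 stayed within 1 standard error of the difference by limma, and Mzt1, Homer2, BC065397 and Cycs moved to -0.55, -0.32, -0.29 and -0.13 log2 when probe sets were averaged. Leave-one-array fits were limited to 1 residual degree of freedom, and the lone array was assumed to vary like the others. No paired analysis was possible because each group is 1 array.

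With small RNA genes left out, 25 genes were higher and 14 lower in all 3 arrays, and 61 stood in rising and 41 in falling order, an alternative chosen after seeing the data, as was leaving out the 0.5M or 1M array for these counts and the list shifts. The filter fixes how many genes are tested, and many counts moved with it. Without it, genes at least 0.5 log2 higher and lower numbered 138 and 139 at 0.5M, 354 and 245 at 2M, and 55 and 24 in all 3 arrays, with 640 higher and 318 lower at 1M. Ordered genes were then 167 rising and 78 falling, the correlation of differences was 0.51 for 0.5M with 1M and 0.63 for 0.5M with 2M, and limma called 1 gene higher in tumour-bearing arrays. At the 60th percentile the counts were 29 and 18 at 0.5M, 68 and 98 at 2M, 85 higher at 1M, 16 higher in all 3, and 28 rising and 27 falling in order, with 2 limma calls. How far the values of the probe sets lie above background was not measured here.

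By construction the size threshold moved all counts. At 0.3 log2, 404 genes were higher and 361 lower at 0.5M, 1233 and 935 at 1M, 725 and 715 at 2M, and 211 and 149 in all 3, with 238 rising and 192 falling in order. At 1 log2 they were 10 and 0, 10 and 13, 17 and 8, and 9 and 0, with 6 rising and 4 falling.

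Leaving out an array gave 38 to 81 genes higher and 21 to 56 lower in all arrays left, where fewer arrays must pass. The extremes of 81 and 56 came without the 0.5M array, and without the 2M array the lower count was 24. Limma calls in the tumour comparison ranged from 3 to 6, the 3 without the 1M array. They shared 4 of the 6 genes without the 0.5M array and 4 without the 2M array, Osmr and Gm10874 being lost in both, and all 6 under loess, median centring, averaged probe sets and the robust prior. Trend calls ranged from 0 to 28 higher and 0 to 30 lower, with the most without the 1M array, and the robust prior gave 2 lower; the cause was not tested. Lists shifted higher ranged from 5 to 6 and lower from 3 to 6 without 1 array; the lists of 3 higher and 5 lower became 5 and 3 with members past the filter only, and 6 were higher by the mean of members; the cause was not tested.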

Other observations

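All tests in this part, and the 4 gene lists it uses, were chosen after the data were seen. Genes of cholesterol synthesis were lower in tumour-bearing hypothalamus. Hsd17b7, which reduces sterol intermediates, was -0.51, -0.51 and -0.77 log2 from control at 0.5M, 1M and 2M, Tmem97, a sterol-regulated membrane protein, -0.49, -0.56 and -0.60, and Hmgcs1, HMG-CoA synthase, -0.19, -0.40 and -0.71. Of the 21 measured genes 12 were lower and 0 higher in all 3 arrays, with a median of -0.24 log2 (percentile 0). By limma 0 passed over all genes, with 9 at an unadjusted p under 0.05. The hypothesis that cholesterol synthesis transcripts are lower as a group was tested on the 18 genes other than these 3, which had prompted it. Their median was -0.16 log2 (percentile 0), with 13 below control, and -0.13 (percentile 0.54) at 1M, where 10 of the 18 were below control and myelin markers stood at 0.02. The shift may therefore extend beyond the genes that prompted it, as a hypothesis found and tested on the same 4 arrays. A high reading of these genes in the single control pool is not excluded.

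Heat shock protein genes had a median of -0.31 log2 (11 genes, percentile 0), with 9 lower and 1 higher in all 3 arrays, and 0 passed limma in the tumour comparison by either adjustment, with 4 at an unadjusted p under 0.05. Chordc1 was -0.39, -1.19 and -0.32 log2 from control and Hspe1 -0.32, -0.82 and -0.58, whereas Hspb1 was 0.34, 0.40 and 1.02 higher. MHC class II genes had medians of -0.16, 0.01 and -0.45 log2 at 0.5M, 1M and 2M (7 genes, percentile 0.01 for the mean over arrays), with Cd74 at -0.96, H2-Aa at -0.77 and H2-Ea at -1.10 at 2M. Cd74 and H2-Aa lay below the filter value. Without the 2M array the list median was -0.07 log2 (percentile 4.56), inside the random range. The 5 neutrophil genes had a median at percentile 76.3.

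The 130 small RNA genes past the filter had median differences of 0.04, 0.14 and 0.10 log2 at 0.5M, 1M and 2M, against 0.00, 0.04 and 0.01 for the other genes. Directly between tumour-bearing arrays, 49 genes were at least 0.5 log2 higher and 104 lower at 1M than at 0.5M, 26 and 31 at 2M than at 0.5M, and 62 and 63 at 2M than at 1M.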
